A study of Mus musculus with 6 samples.

How the data were processed

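RNA-seq libraries were compared from regulatory T cells of mouse bone marrow, 3 from control mice and 3 from mice 3 months after irradiation, all wild type. Per the series' design text the cells were gated as CD3-positive, CD4-positive, NK1.1-negative and Foxp3-positive. Per the labels' protocols RNA was extracted with a low-input column kit and libraries were made with a stranded mRNA kit. Per the submitters' processing notes fastp, HISAT2 and StringTie were used with the builds GRCm38 and mm10, and versions, settings and the annotation release are not given in the sources used here.

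The authors deposited 1 value per gene and library, which was read as FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) although the file headers name only the gene and the sample. The column totals differed between libraries, while the sum of value times exonic length stayed between 1465010 and 1476170 kilobase units, and low values were whole multiples of a step per gene. All 6 tables listed the same 15483 genes, of which 15391 have a symbol in RefSeq GRCm38.p6 and 14960 in GENCODE M21. Each gene was above 0 in at least 1 library and 12309 were above 0 in all 6. The tables used here list 0 mitochondrially encoded genes and 0 immunoglobulin or T cell receptor segment genes, so these were not analysed here. Coordinates are from GENCODE M21 on GRCm38, or from RefSeq GRCm38.p6 where that is said.

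The values carry no read counts and the absolute depth is unknown. Relative depth was recovered from genes below 0.1 FPKM, as the ratio between libraries at which most values were ratios of whole numbers up to 6 within 0.001. Against control replicate 1 the depth was 98.5% and 103% in control replicates 2 and 3, and 92.2%, 92.7% and 81.6% in irradiated replicates 1, 2 and 3. Between 128 and 209 low genes in each library met that ratio, out of 225 to 341 compared. The irradiated libraries were thus shallower, which widens the error of genes near the floor.

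Samples were grouped by the treatment label and the replicate numbers of the sample titles were used only as names. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are irradiated minus control on the log2(FPKM + 1) scale, which understates the change of low genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

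There were 37 gene lists, written before the data were examined, on T cell identity, ageing and DNA damage, metabolism, signalling and markers of other marrow cells. The 36 with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, which compares a list with all other genes. Camera was repeated with an estimated correlation, and fry was run, which asks whether the genes of a list move on balance one way. The list of mitochondrially encoded genes had 0 members. Members were counted as risen or fallen by the limma test over all genes and again adjusted over the list alone.

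Named genes followed a rule written before the data were examined. It took the 12 largest changes per direction among genes past the threshold whose groups did not overlap and whose higher mean was at least 5 FPKM, leaving out unnamed models and pseudogenes. It added up to 4 members of each list with the lowest p, and 9 genes that were always named. Genes outside the rule are said to be chosen after their values were seen.

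The gene and list tests were tested on simulated data drawn from the spread of these 10666 genes with 200 changed genes in each of 5 draws. Of genes changed by a log2 fold of 0.5, 45.0% were recovered, and of those changed by 1, 85.0%. Of the calls, 2.64% were false and 0 had the wrong sign. A list shifted by 0.3 was called in 5 of 5 draws and an unchanged list in 0. Genes were drawn independently of each other, so these draws cannot show how the list test behaves where genes are correlated.

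Alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, only genes above 0 in all 6 libraries, median-of-ratios scaling, quantile normalization, array weights, no trend, a threshold of unadjusted p under 0.05 with a log2 fold of at least 1, a replicate block, and leaving out each library in turn. Scaling each library to the geometric mean of its T cell core genes was chosen after seeing the data, for the T cell and Treg genes only.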

Results

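The data were FPKM values of 15483 genes in 6 RNA-seq libraries of sorted mouse bone marrow Tregs, the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. There were 3 control libraries and 3 libraries from 3 months after irradiation, which the series title links with premature ageing. Column totals were 470375, 467925 and 451444 FPKM in control replicates 1, 2 and 3, and 480854, 482747 and 485365 FPKM in irradiated replicates 1, 2 and 3. On average 13911 ± 157 genes (SD, n = 3) were above 0 in control libraries and 13523 ± 19.3 in irradiated libraries. On log2(FPKM + 1) over the tested genes, Pearson's r between libraries was 0.989 to 0.992 within groups and 0.974 to 0.978 between groups, across genes that are not independent replicates.

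The most abundant transcripts in all 6 libraries were those of the granulocyte genes S100a8 and S100a9. S100a8, which encodes a subunit of the neutrophil protein calprotectin, stood at 25283 ± 1249 FPKM (SD, n = 3) in control and 39026 ± 427 FPKM in irradiated libraries. S100a8 and S100a9 together made up 9.80% ± 0.179 of the summed FPKM in control and 14.3% ± 0.316 in irradiated libraries, a share not weighted by transcript length. Foxp3 stood at 22.6 ± 1.93 FPKM in control and 12.6 ± 0.795 FPKM in irradiated libraries, and Cd3e, a chain of the T cell receptor complex, at 39.5 ± 2.93 and 24.96 ± 1.42 FPKM. Klrb1c, which encodes the NK1.1 antigen that the gate excluded, was at 17.9 ± 1.36 and 9.52 ± 0.420 FPKM. Transcripts of eosinophils (Prg2), myeloid cells (Lyz2), erythroid cells (Hbb-bs), B cells (Cd79a) and CD8 T cells (Cd8a) were measured too, and Lyz2, Cd79a, Cd8a and S100a9 were chosen for display after their values were seen.

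**Figure D1:**
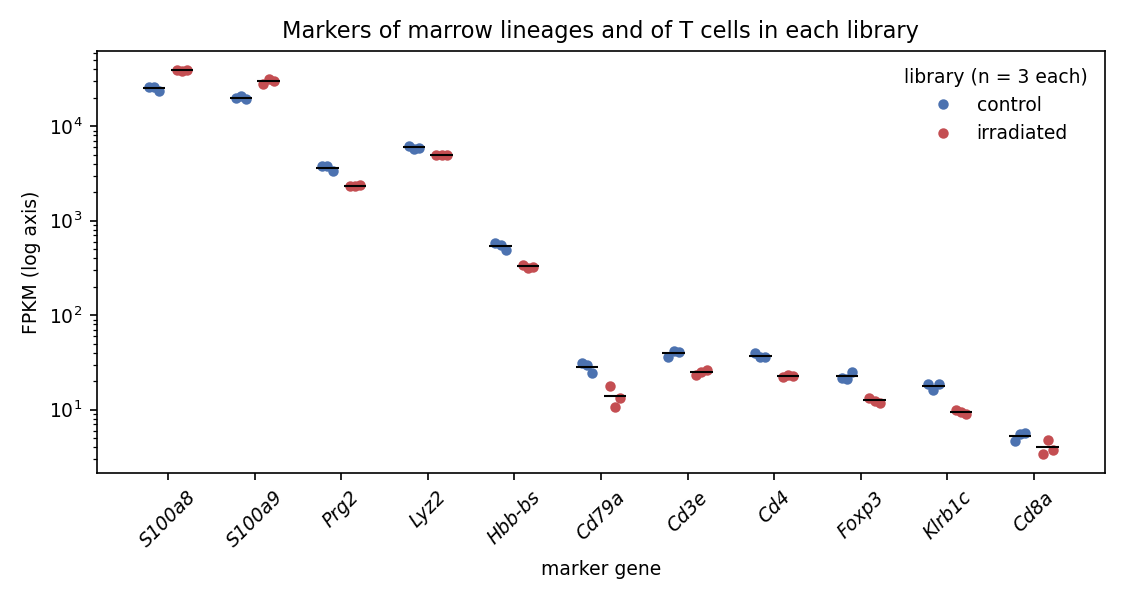
FPKM on a log axis for 11 marker genes, with a point for each library (control in blue, irradiated in red, n = 3 each) and a bar at each group mean. S100a8 lies between 23847 and 26122 FPKM in control libraries, while Foxp3 has a control mean of 22.6 FPKM.

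The comparison of irradiated with control libraries asks how the Treg transcriptome differs 3 months after irradiation. Type I interferon response genes fell throughout their list, and most marker genes of B cells, macrophages and T cells fell too, as did Foxp3, while most granulocyte markers and Jchain rose. Of 10666 genes tested with limma, 671 were higher and 1100 lower in irradiated libraries, which is 16.6% of those tested. Of these, 40 were higher and 172 lower by a log2 fold of at least 1. In 1756 of the 1771 called genes the 3 irradiated values lay beyond all 3 control values, and over all tested genes this held for 33.6%, where chance gives 10%. The median log2 change of the tested genes was -0.02 and the median standard error 0.11. Without control replicate 2 the counts were 414 higher and 709 lower.

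The largest rises included stefin genes and Jchain. The stefins encode cysteine protease inhibitors, and the values were highest for Cstdc5 (log2 change 2.32 ± 0.19 SE), Stfa2 (2.26 ± 0.12), Stfa3 (1.95 ± 0.21) and Stfa1 (1.72 ± 0.14), near-identical copies on chromosome 16 whose reads can be shared, so the values of single copies are uncertain. Jchain, which joins the units of IgM and IgA (chromosome 5, 88519809 to 88527891), rose from 128.7 ± 6.91 to 410.0 ± 9.55 FPKM, a log2 change of 1.67 ± 0.05 with an adjusted p of 3.02e-08. Prok2, a secreted ligand made by neutrophils, rose by 1.91 ± 0.20, the lipase gene Lipg by 1.79 ± 0.12, and Wfdc17 from 63.6 ± 7.16 to 180.6 ± 11.03 FPKM. Upp1 (uridine phosphorylase), Steap4 (a metalloreductase), Asprv1 and Mcam rose by between 1.28 and 1.42. The largest falls included B lineage and interferon genes. Igll1, the surrogate light chain of precursor B cells (chromosome 16, 16860671 to 16863985), changed by -2.97 ± 0.16, from 7.59 ± 0.328 to 0.108 ± 0.188 FPKM. Spib, Dntt and Ly6d, genes of B cells and their lymphoid precursors, changed by -2.26, -2.24 and -2.08. Cd5l and Hpgd, genes of tissue macrophages, changed by -2.19 and -2.11.

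T cell identity genes were lower after irradiation. Of 19 tested T cell core genes 0 rose and 16 fell (17 adjusted over the list alone), with a median log2 change of -0.63 (camera adjusted p = 2.37e-13). Camera with an estimated correlation gave that list an adjusted p of 0.0141. Cd3g fell from 89.0 ± 7.25 to 44.4 ± 2.22 FPKM (log2 change -0.98 ± 0.07), Cd2, an adhesion receptor, changed by -0.90 ± 0.06, Ptprcap by -0.76 ± 0.09, Cd4 by -0.69 ± 0.07 and Cd3e by -0.64 ± 0.08. In the same libraries the markers of granulocytes rose (15 of 21) and Klrb1c changed by -0.84 ± 0.09. The core list also holds Ptprc and Lcp2, which other leukocytes transcribe too, and these changed by -0.10 and -0.34.

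Of 28 tested Treg signature genes 0 rose and 17 fell (22 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 3.85e-10). Camera with an estimated correlation gave that list an adjusted p of 0.0150. Foxp3 (chromosome X, 7573644 to 7595245) changed by -0.80 ± 0.09 with a limma adjusted p of 0.000119. Il2rb, the beta chain of the IL-2 receptor, changed by -0.68 ± 0.06, the inhibitory receptor gene Tigit by -1.37 ± 0.13, and Penk and Cd83 by -1.73 ± 0.19 each. Ctla4, a checkpoint receptor of Tregs, changed by -0.62 ± 0.15 (adjusted p = 0.0136), and this call was lost in 2 of 6 fits that left out a library, at adjusted p up to 0.0532. Ikzf2, which encodes Helios, changed by -0.41 ± 0.12 (adjusted p = 0.0438) and lost its call in 4 of those 6 fits, at adjusted p up to 0.135. Il2ra, the alpha chain of the IL-2 receptor, had a log2 change of -0.52 ± 0.18 and did not pass (adjusted p = 0.0802). Cd83 and Penk are not specific to T cells, and markers of dendritic cells (10 of 13) and B cells (14 of 15) fell in the same libraries.

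Scaled to the T cell core genes, an alternative chosen after seeing the data, 5 Treg signature genes were higher and 7 lower. On that scale Foxp3 changed by -0.24 ± 0.09 (adjusted p = 0.0228), Tigit by -0.86 ± 0.13, Penk by -1.30 ± 0.20 and Cd83 by -1.27 ± 0.20. The core genes themselves ran there from -0.41 for Cd3g to 0.48 for Ptprc, so Foxp3 lay within their range. Since Ptprc is not specific to T cells, that range is not one of T cells alone. Il2rb, at -0.11 ± 0.06 (adjusted p = 0.139), and Ctla4, at -0.09 ± 0.14, did not pass there, and Ikzf2 turned to 0.12 ± 0.12. The mean of the Treg signature minus that of the T cell core was -1.74 ± 0.015 (log2, SD, n = 3) in control and -1.79 ± 0.024 in irradiated libraries, a difference of -0.05 with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows.

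**Figure D2:**
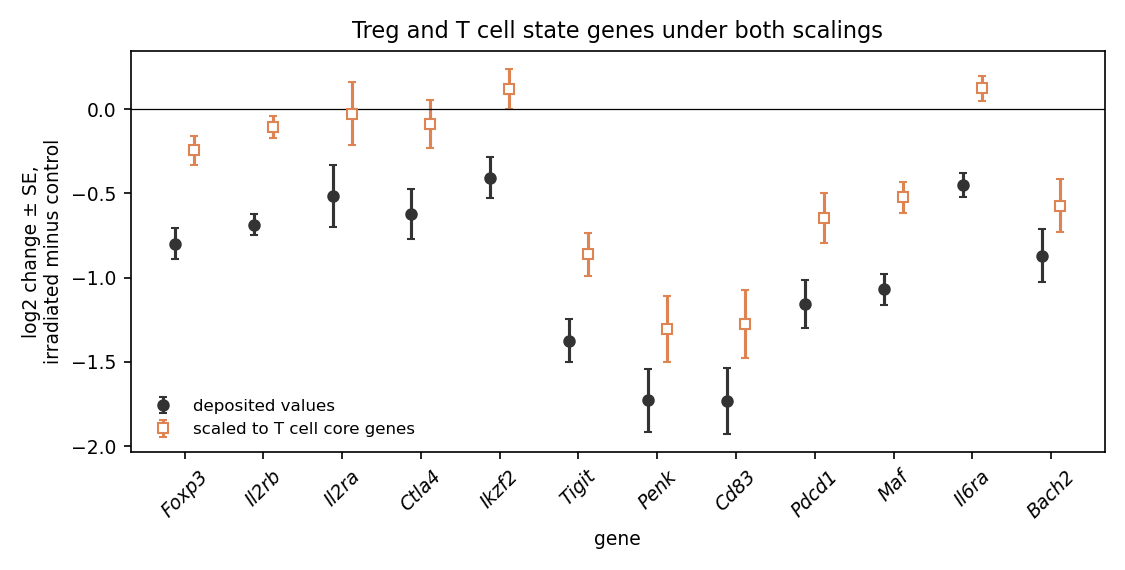
Log2 change (irradiated minus control, with SE bars, n = 3 each) of 12 Treg and T cell state genes, on the deposited values (filled circles) and scaled to the T cell core genes (open squares). Foxp3 moves from -0.80 to -0.24 and Ikzf2 from -0.41 to 0.12, while Tigit moves from -1.37 to -0.86 and stays below 0.

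Of 30 tested Treg effector and suppressive genes 4 rose and 18 fell (5 and 19 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 9.31e-05, and adjusted p = 0.0648 with an estimated correlation). Maf, a transcription factor of effector Tregs, changed by -1.07 ± 0.09 and the chemokine gene Ccl5 by -0.70 ± 0.06. Anxa1 rose from 888 ± 8.26 to 1664 ± 13.5 FPKM and S100a6 from 369 ± 2.67 to 706 ± 11.7 FPKM, and both are also transcribed in granulocytes, whose markers rose. Of 13 tested inhibitory receptor and exhaustion genes 1 rose and 9 fell (1 and 10 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 9.48e-05). Pdcd1, which encodes PD-1, changed by -1.16 ± 0.14, Tox by -1.17 ± 0.14 and Havcr2 by -0.87 ± 0.16. Scaled to the T cell core genes, 13 effector genes rose and 8 fell (median 0.04), and 2 inhibitory receptor genes rose and 5 fell (median -0.09). On that scale Maf kept its call (-0.52 ± 0.09, adjusted p = 0.000379), while Ccl5 (-0.12 ± 0.06, adjusted p = 0.0966) lost it. Markers of monocytes and macrophages (16 of 21) fell in the same libraries, and which cells gave the Maf transcripts was not tested.

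Of 21 tested naive and central T cell genes 1 rose and 10 fell (1 and 11 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.000739) that turned to 0.24 when scaled to the T cell core, where 9 genes rose and 1 fell. On the deposited values camera with an estimated correlation gave that list an adjusted p of 0.0485. Bach2, a repressor that keeps T cells quiescent and is transcribed in B cells too, changed by -0.87 ± 0.16, at low values (1.85 to 0.562 FPKM). B lineage markers (14 of 15) fell in the same libraries, and which cells gave the Bach2 transcripts was not tested. Il6ra (-0.45 ± 0.07) and Ms4a4b (-0.47 ± 0.08) fell on the deposited values and were at 0.12 and 0.11 on the T cell scale, where Bach2 was at -0.57 ± 0.16. Actn1, which encodes a cytoskeletal protein of many cells, rose by 0.30 ± 0.05. Of 13 tested helper lineage genes 2 rose and 5 fell (2 and 5 adjusted over the list alone), and the list did not pass (median -0.36, camera adjusted p = 0.105) and had a median of 0.10 on the T cell scale, where 4 genes rose and 2 fell. Gata3 changed by -0.93 ± 0.16 and Ifng by -0.97 ± 0.20, and Tnf, which myeloid cells make too, rose by 0.80 ± 0.17. Of 26 homing and adhesion genes 0 rose and 15 fell (16 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 5.04e-06), among them the chemokine receptor gene Cxcr3 (-0.72 ± 0.07, and -0.15 ± 0.07 without a call on the T cell scale) and Itgb7 (-0.48 ± 0.06). Neutrophil markers rose in the libraries in which the naive and central T cell list and the homing list fell.

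Interferon response genes fell as a block. All 35 tested type I interferon genes fell, also adjusted over the list alone, with a median of -1.28 (camera adjusted p = 7.89e-39, and adjusted p = 0.00667 with an estimated correlation). Ifi27l2a (chromosome 12, 103442167 to 103443680) fell from 227.7 ± 12.4 to 49.3 ± 5.19 FPKM, a log2 change of -2.19 ± 0.08 with a limma adjusted p of 3.49e-08. Irf7, the transcription factor that amplifies interferon production, changed by -1.88 ± 0.08, Slfn5 by -1.66 ± 0.08 and Lgals3bp by -1.28 ± 0.06. Isg15, a ubiquitin-like protein, changed by -2.19 ± 0.23, Usp18, which removes it from its targets, by -2.22 ± 0.13, Ifit3 by -2.13 ± 0.12 and Oas1g, one of several similar Oas1 copies, by -2.46 ± 0.14. In the same libraries Siglech, a gene of plasmacytoid dendritic cells, changed by -1.95 ± 0.13, and the macrophage genes C1qa, C1qb and C1qc fell.

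**Figure D3:**
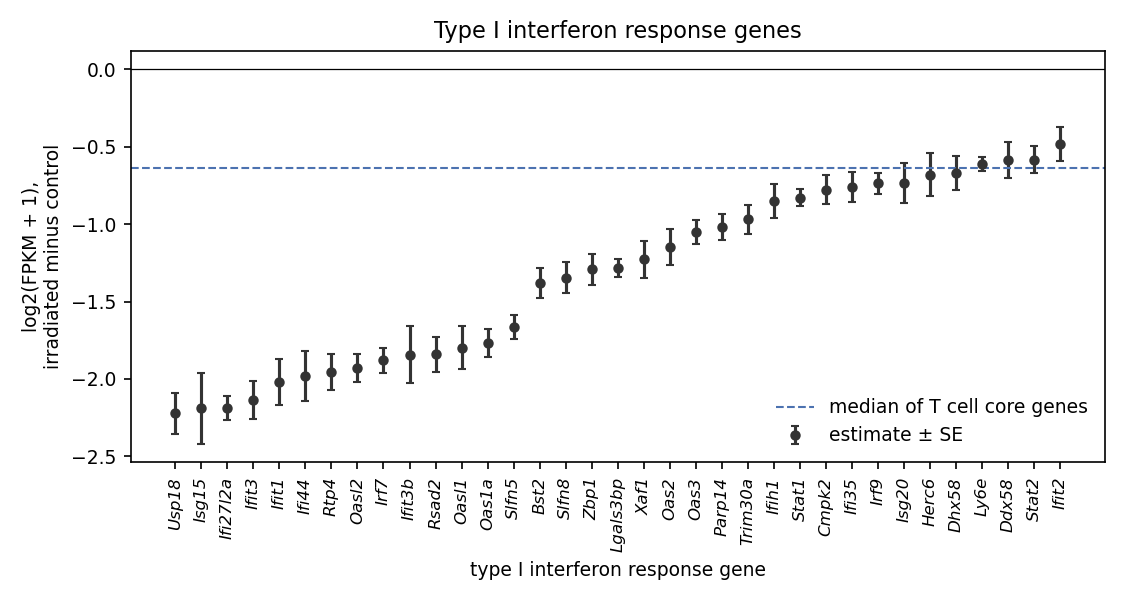
Log2 change (irradiated minus control, with SE bars, n = 3 each) of the 35 type I interferon response genes, in order of change, with a dashed line at the median of the T cell core genes, -0.63. The genes range from -2.22 for Usp18 to -0.48 for Ifit2.

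Other signalling lists moved less. Of 24 NF-kB targets 1 rose and 10 fell (1 and 13 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.000203), including Bcl2a1b (-1.43 ± 0.20), a member of a family of similar copies, and Icam1 (-0.50 ± 0.08). Of 30 immediate early genes 3 rose and 13 fell (4 and 16 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00573, and adjusted p = 0.436 with an estimated correlation). Without control replicate 3 that list had an adjusted p of 0.102. Nr4a1, induced by T cell receptor signals, changed by -0.75 ± 0.12, while Fosb and Ier3 rose by 1.01 ± 0.15 and 0.99 ± 0.14. Of 30 heat shock and unfolded protein genes 1 rose and 10 fell (4 and 13 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00376, and adjusted p = 0.0585 with an estimated correlation). The chaperone genes Hspa8 and Hsph1 changed by -0.44 ± 0.04 and -0.77 ± 0.10. Of 34 autophagy and lysosome genes 4 rose and 9 fell (7 and 12 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0225, and adjusted p = 0.238 with an estimated correlation), and the cathepsin genes Ctsb, from 549.5 ± 23.4 to 274.0 ± 4.27 FPKM, and Ctss (-0.70 ± 0.05) are abundant in macrophages, whose markers fell too.

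Few p53 targets, senescence regulators and DNA repair genes changed, while genes of the secretory phenotype of senescent cells moved in both directions. Of 30 p53 targets 2 rose and 2 fell, also adjusted over the list alone, and the list did not pass (median -0.05, camera adjusted p = 0.790). The DNA damage gene Gadd45a rose by 0.45 ± 0.08 and Ddb2 by 0.46 ± 0.12, while Tap1, which interferon also induces, changed by -0.57 ± 0.06 and Btg2 by -0.51 ± 0.08. The Ddb2 call was lost in 4 of 6 fits that left out a library, at adjusted p up to 0.1. Cdkn1a, the p21 cell cycle inhibitor, stood at 10.1 ± 2.19 FPKM in control and 7.07 ± 1.88 FPKM in irradiated libraries and did not pass (log2 change -0.47 ± 0.18, adjusted p = 0.107). Cdkn2a, which encodes p16 and was always to be named, was below the mean of 1 FPKM and was not tested. Of 23 senescence regulators 1 rose, Cdkn2d at 0.50 ± 0.06, and 0 fell, also adjusted over the list alone (median -0.13, camera adjusted p = 0.278). Of 29 genes of the secretory phenotype of senescent cells 7 rose and 8 fell (9 and 11 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.914), with a median of 0.03 and a mean of -0.13. Il1b, an inflammatory cytokine of myeloid cells, changed by -1.33 ± 0.07, and Mmp9, a neutrophil protease, rose by 0.66 ± 0.04. Of 57 DNA repair genes 0 rose and 1 fell, Xrcc6 at -0.39 ± 0.11, a call lost in 4 of 6 fits that left out a library (adjusted p up to 0.131), and 0 passed adjusted over the list alone. That list did not pass (median -0.02, mean 0.01, camera adjusted p = 0.557, direction up, against down with fry). Of 31 apoptosis regulators 0 rose and 4 fell (0 and 3 adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 0.250. By fry, which does not compare a list with other genes, p53 targets (adjusted p = 0.00929), secretory phenotype genes (0.0397) and apoptosis regulators (0.0163) were lower. The p53, senescence and repair genes were read in libraries in which granulocyte genes had the most abundant transcripts.

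Some cell cycle and glycolysis genes rose by small amounts, in libraries in which neutrophil markers rose too. Of 50 cell cycle genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 2.9e-05, and adjusted p = 0.0684 with an estimated correlation), among them Rrm2, a subunit of ribonucleotide reductase (0.34 ± 0.05), and Cdca3 (0.43 ± 0.08). Of 23 glycolysis genes 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 1.59e-05). Camera with an estimated correlation gave that list an adjusted p of 0.04997, just under the threshold. The glucose transporter gene Slc2a3 rose by 0.53 ± 0.06 and Hk3, a hexokinase of myeloid cells, by 0.45 ± 0.05. Of 76 genes of nuclear-encoded oxidative phosphorylation 9 rose and 0 fell, also adjusted over the list alone, and the list did not pass (median 0.00, camera adjusted p = 0.0950). Atp5l, a subunit of ATP synthase, was among the genes that rose, at 0.27 ± 0.06. That list passed with median-of-ratios scaling (adjusted p = 0.02915) and without control replicate 1 (0.00803) or 2 (0.02109), and its direction turned without control replicate 3. Of 84 cytosolic ribosomal protein genes 0 rose and 10 fell (8 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 2.9e-05, and adjusted p = 0.559 with an estimated correlation), and it did not pass by fry (adjusted p = 0.222). Of 31 antioxidant genes 5 rose and 5 fell (5 and 6 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.914), and G6pdx rose by 0.66 ± 0.05 while Hmox1, the haem-degrading enzyme of macrophages, changed by -0.85 ± 0.06. Of 33 lipid and cholesterol genes 7 rose and 6 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.373), with a median of 0.06, a mean of -0.03 and the test direction up. The sterol synthesis gene Fdps rose by 0.69 ± 0.07, and the cholesterol exporter genes Abca1 and Abcg1 changed by -1.02 ± 0.13 and -1.01 ± 0.14.

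**Figure D4:**
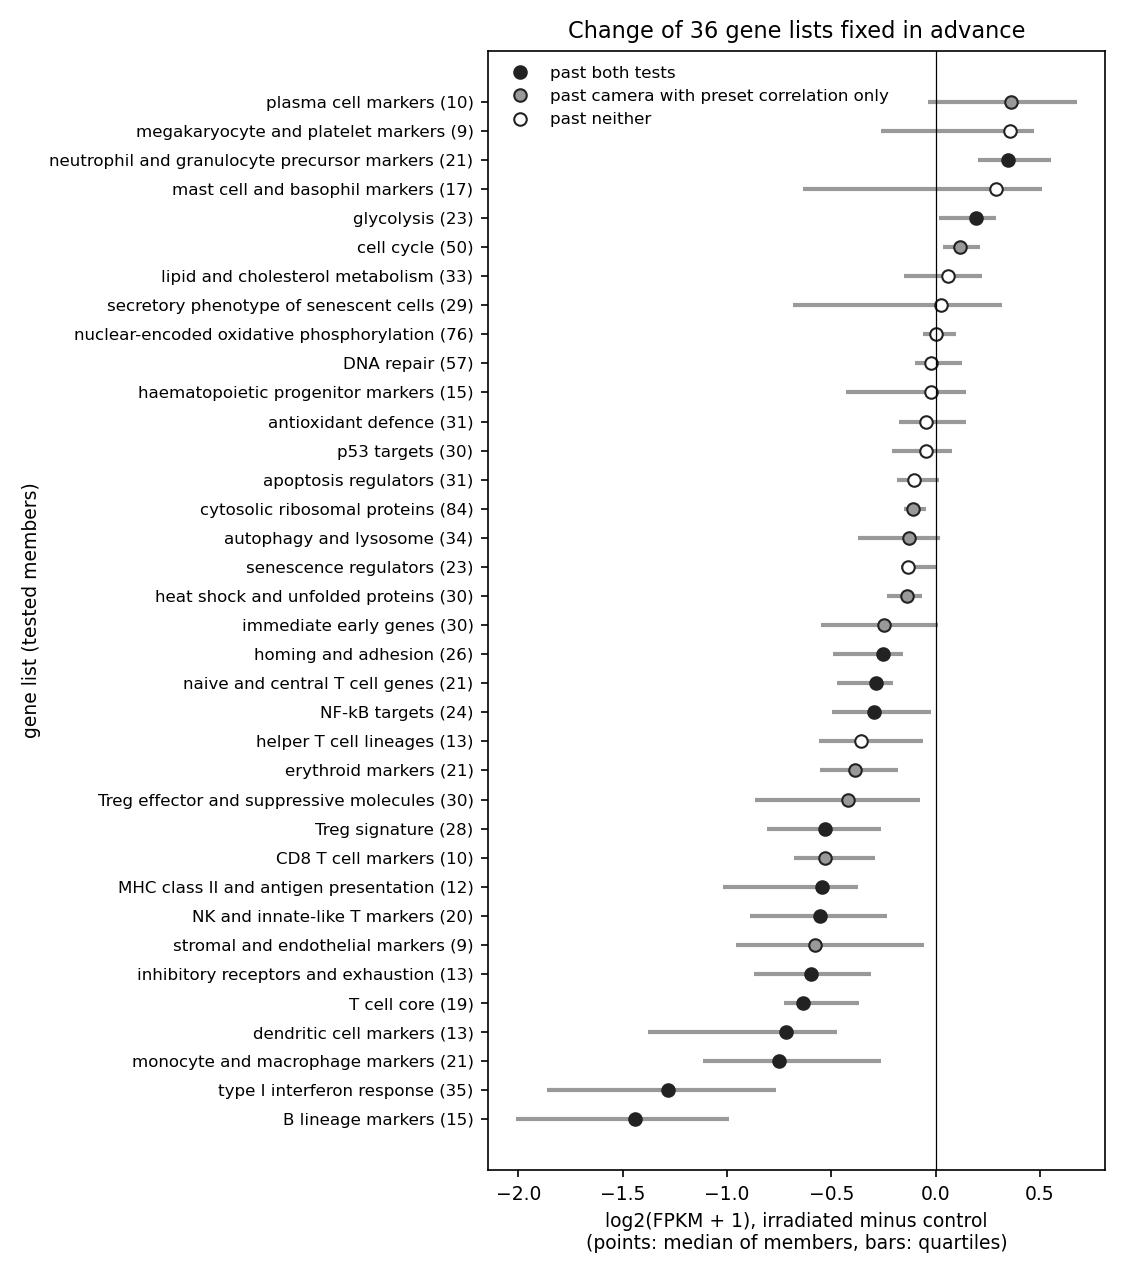
Median (point) and quartiles (bar) of the log2 change of the tested members of 36 gene lists, irradiated minus control, with the number of members in brackets. The lists of B lineage markers (-1.44) and type I interferon genes (-1.28) lie lowest, and plasma cell markers (0.36) highest.

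Markers of other marrow cells moved in both directions. Of 21 neutrophil and granulocyte precursor markers 15 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 2.39e-16). Camera with an estimated correlation, 0.228 for that list, gave an adjusted p of 0.0485, just under the threshold. S100a8 rose by 0.63 ± 0.05, the iron-binding protein gene Lcn2 by 0.55 ± 0.04 and Wfdc21 by 0.75 ± 0.05. Of 21 monocyte and macrophage markers 1 rose and 16 fell, also adjusted over the list alone, with a median of -0.75 (camera adjusted p = 1.06e-13). The complement genes C1qa, C1qb and C1qc changed by -1.83 ± 0.07, -1.76 ± 0.12 and -1.91 ± 0.06, and the adhesion gene Vcam1 by -1.55 ± 0.06. Of 13 dendritic cell markers 0 rose and 10 fell (12 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.2e-09). Of 12 genes of MHC class II antigen presentation 0 rose and 8 fell (9 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 1.22e-07), and H2-Aa changed by -1.17 ± 0.06 and Cd74 by -1.01 ± 0.05. Of 15 B lineage markers 0 rose and 14 fell (15 adjusted over the list alone), with a median of -1.44 (camera adjusted p = 6.67e-15).

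Of 10 plasma cell markers 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.00179, and adjusted p = 0.0585 with an estimated correlation). Besides Jchain these were Derl3 (1.25 ± 0.14), Mzb1 (0.67 ± 0.14) and Xbp1 (0.35 ± 0.06), genes of the secretory pathway of antibody-making cells. Of 21 erythroid markers 0 rose and 10 fell, also adjusted over the list alone, with a median of -0.38 (camera adjusted p = 1.13e-05, and adjusted p = 0.0902 with an estimated correlation), with the globin gene Hbb-bs at -0.71 ± 0.06. Of 20 NK and innate-like T cell markers 0 rose and 11 fell (1 and 12 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 1.13e-05), among them the granzyme gene Gzma (-1.65 ± 0.17). Of 10 CD8 T cell markers 0 rose and 4 fell (6 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.00213, and adjusted p = 0.0585 with an estimated correlation). Of 9 stromal and endothelial markers 0 rose and 5 fell (6 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 0.00671, and adjusted p = 0.147 with an estimated correlation). Of 15 progenitor markers 3 rose and 6 fell, also adjusted over the list alone (median -0.02, camera adjusted p = 0.365), with Gata2 at 0.68 ± 0.06 and Ly6a, an interferon-inducible stem cell antigen, at -1.38 ± 0.08. Of 9 megakaryocyte and platelet markers 1 rose, Itga2b at 0.75 ± 0.08, and 2 fell (3 and 2 adjusted over the list alone; median 0.36, camera adjusted p = 0.278, and 0.04696 without control replicate 1).

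In total 24 of 36 lists passed camera with the preset correlation, 4 higher and 20 lower, and 14 of them, 2 higher and 12 lower, also passed with an estimated correlation. Those 14 were the lists of neutrophil and glycolysis genes among the higher, and of T cell core, Treg signature, naive and central T cell, inhibitory receptor, homing, interferon, NF-kB, MHC class II, macrophage, dendritic, B lineage and NK genes among the lower. Their camera adjusted p with an estimated correlation ran from 0.00667 for interferon to 0.04997 for glycolysis, far above the values with the preset correlation. By fry 29 lists passed, among them also the helper (adjusted p = 0.0163) and progenitor (0.00294) lists as lower and the megakaryocyte list (0.0263) as higher.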

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

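The alternatives were chosen before the data were examined, except scaling to T cell core genes. The threshold of unadjusted p under 0.05 with a log2 fold of at least 1 gave 40 higher and 172 lower genes, fewer by its own construction. Leaving out a library in turn gave 414 to 684 higher and 709 to 968 lower genes, lowest for both without control replicate 2, with fewer samples in each fit. All other settings kept both counts within 1.5 times the reported ones, and the share of calls that were higher went from 37.9% to 46.4% with median-of-ratios scaling and 46.3% with quantile normalization. Lists past the threshold numbered 14 with an estimated correlation, and 23 to 26 when a library was left out. Of the 150 called named genes, 131 kept their call in every fit without a library in which they were tested. Without control replicate 1 and without control replicate 2, 149 of the 150 were tested. S100a8, the most abundant gene in each library, was at 0 with quantile normalization, which sets that rank to 1 value.

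In the planned settings directions turned only in lists that did not pass, and the cause was not tested. Scaled to the T cell core, the medians of the naive and central, Treg effector and helper lists turned, to 0.24, 0.04 and 0.10. For the list of antioxidant defence the mean was 0.00941 with median-of-ratios scaling and -0.0402 to -0.0128 when a library was left out, with the test direction turned without control replicate 1 and without irradiated replicate 2. For the secretory phenotype of senescent cells the mean was -0.143 to -0.0974 when a library was left out, with the test direction turned without control replicate 1 or 3. With the replicate block that direction turned too, at an unchanged mean of -0.128. For nuclear-encoded oxidative phosphorylation the mean was -0.0104 to 0.0455 when a library was left out, and the list for DNA repair, with a mean of 0.00651, turned with fry. When scaled to T cell core genes, 17 of 27 called members of the T cell and Treg lists, named through them or always named, kept their call. Another 7 lost it (Cd4, Cd3e, Ptprcap, Il2rb, Ctla4, Ccl5 and Tbx21) and 3 turned, with gene Il6ra at 0.123, gene Ms4a4b at 0.107 and gene Ikzf2 at 0.119. Members named only through other lists are not in these counts. Of those, Cxcr3 (limma adjusted p = 0.0799) and Eomes (0.377) lost their call and Gzma (0.000216) kept it. Cd4, Cd3e and Ptprcap belong to the core itself, which the scaling centres by construction.

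With the replicate number as a block 558 genes were higher, 948 lower and 24 lists passed. Same-numbered libraries did not deviate together (correlations 0.0111, -0.0423 and -0.0228), and not every library correlated best with its own number, so the numbers were not read as pairs.

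The absolute depth is unknown, and the shallower irradiated libraries limit what can be seen in genes near the floor. Because relative values carry no total RNA per cell, changes are relative to the other transcripts of each library.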

Other observations

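The mast cell and basophil list, which also held eosinophil genes, split into opposite parts. Of its 17 tested members 8 rose and 5 fell (8 and 6 adjusted over the list alone), and as a whole it did not pass (median 0.29, camera adjusted p = 0.267, adjusted p = 0.535 with an estimated correlation). The basophil protease gene Prss34 rose from 1294 ± 37.8 to 1930 ± 39.5 FPKM (SD, n = 3), and the basophil genes Mcpt8 (log2 change 0.50) and Fcer1a (0.68), chosen after their values were seen, rose too. The eosinophil granule genes Prg2 (-0.63 ± 0.05 SE), Ear1 (-0.83 ± 0.05) and Ear2 (-0.81 ± 0.05) fell, as did Epx (-0.71) and Prg3 (-0.92), also chosen after their values were seen, and Ear1 and Ear2 are similar copies that can share reads. All 6 stefin genes tested rose, from 0.75 for Stfa2l1 to 2.32 for Cstdc5, and they lie on chromosome 16 between 36156811 and 36455392 in RefSeq GRCm38.p6; this group was chosen after its values were seen.

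All tests of explanations below were chosen after the results were seen. Granulocyte and other lineage transcripts were abundant in libraries labelled Tregs, although the gate on CD3, CD4 and Foxp3 would remove such cells. Irradiation cannot be their origin, since S100a8 and S100a9 took at least 9.62% of the summed FPKM in every control library. RNA from other bone marrow cells is a candidate explanation. All 21 granulocyte markers exceeded 10 FPKM in all 6 libraries, as cells that bring all their abundant transcripts would give. The markers were fixed in advance but the bound of 10 FPKM was not. This count largely restates that granulocyte transcripts were abundant, so it cannot decide the question. Whether other marrow cells passed the sort or their RNA adhered to sorted cells, and whether a less enriched sample lies behind the values, was not tested.

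T cell core and Treg signature genes fell together, the core by -0.59 ± 0.02 (SE). Weighted by exonic length, the 21 listed granulocyte genes took 5.40% of the total in control and 7.28% in irradiated libraries. Their larger share forces a log2 shift of only -0.0291 on all other genes, far less than the shift of the core. This value leaves out all other granulocyte transcripts. It therefore cannot decide whether more granulocyte RNA as a whole lowered the T cell genes. A lower share of T cells with all other cell types unchanged among themselves is argued against. The B lineage median lay below the neutrophil median by -1.79, where such a change raises all other types alike. A lower share of T cell RNA, with several other cell types changing too, cannot be told apart from an equal fall per cell: the Treg signature differed from the core by -0.0497, with 5 members higher and 7 lower once scaled, while the naive and helper lists lay above it by 0.25 and 0.29. A change per cell of Foxp3, Tigit and Penk, which fell beyond the mean of the core, was not tested. Once scaled, Foxp3 (-0.24) lay within the range of the core genes, of which Cd3g, at -0.41, fell further. The mean of the core includes Ptprc, which is not specific to T cells.

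Type I interferon genes fell further than the T cell genes, by an excess of -0.762 in log2 over the T cell core against an SD between libraries of at most 0.0522, so a lower share of T cell RNA alone cannot give it. A lower interferon response in the irradiated group stays open, since the median of the list lay above that of the B lineage list, the lowest of the cell type lists, by 0.158. Fewer macrophages or other cells rich in these transcripts cannot be told apart from it. Of the 35 genes, 11 fell further than the mean of C1qa, C1qb and C1qc (-1.83). The macrophage gene Cd5l (-2.19) and the plasmacytoid dendritic cell gene Siglech (-1.95) did so too, while the median of the macrophage markers was -0.75. Igll1, of precursor B cells, fell further still, to 0.108 FPKM, and says little about cells that carry interferon genes. The fall of the interferon genes may be a difference between the groups in marrow composition, in signalling or in both. Since the replicates may be technical, a difference between single preparations of the groups cannot be told apart from these.

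With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 671 higher and 1100 lower genes, and the highest of the other splits gave 0 of each, so that only 1 of 10 splits reached each count. For the lists, 1 of 10 splits reached the 24 of the real split, and the highest other gave 15, with 9 the lowest. With an estimated correlation the real split gave 14 lists and the others 0. Every other split mixes libraries of both groups, so the group difference enters its spread. The counts of those splits therefore do not show what groups without a difference would give.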
